A study of Caenorhabditis elegans with 12 samples.

How the data were processed

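The study sequenced ribosome-depleted total RNA from early Caenorhabditis elegans embryos. Per the labels, embryos from before the bean stage were collected 60 to 65 h after synchronization at the L1 larval stage, from worms grown at 20 °C, and 5 µg of total RNA went into depletion. The genotypes were N2, met-2(n4256), set-25(n5021) and met-2(n4256); set-25(n5021), with 3 libraries each, 12 in all. Columns were assigned to genotypes by their names. The columns carry letters and the sample titles carry numbers, and no source pairs them, so the design has no replicate block. The labels name 2 independent biological replicates where 3 libraries are listed, and which libraries share an origin is not given in the sources used here.

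The authors deposited a table of counts per gene and a table of counts per repeat family, both raw counts in whole numbers with no scaling. A further column of the deposited tables, in other units, gives a width in bases, which follows the gene span with introns: in 6501 genes whose exons cover under 50% of the span, its median was 0.990 of the span and 2.57 of the exon length. Aligner, genome build, counter, strand setting and the handling of reads that fit several places are not given in the sources used here. The gene table held 27904 genes by sequence name, of which 27163 (97.3%) were found in the Ensembl annotation of WBcel235, and 16842 had a gene symbol. Positions are from that annotation. The repeat table held 392 families, sorted into classes by family name. None of 12 mitochondrially encoded genes was found in the gene table, and ribosomal RNA genes took 1.97 to 5.27% of counts per library.

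Genes were tested with edgeR 4.0.16 (R 4.3.3) in 1 quasi-likelihood fit of all 12 libraries, with robust dispersion, TMM scaling and its filter for low counts by genotype. All tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as threshold and no fold threshold. 14260 genes and 257 repeat families passed the filter. Repeat families were fitted apart, with the effective library sizes of the gene table. Contrasts were each mutant against N2, the mutants against each other and the interaction. CPM is TMM-scaled, the SE is taken from the log2 CPM of the replicates with a prior count of 2, and genes with 3 counts or fewer in a group are given as ratios with 95% counting intervals or, with none, against a floor of 3 counts over the group. Fitted with 3 libraries per group, genes changed 2-fold were recovered in 68.7 to 71.6% of cases and those changed 4-fold in 97.0 to 98.5% when tested on simulated data, with 1.59 to 5.84% of calls false. In simulated repeat counts 95.0% of 2-fold and 90.0% of 4-fold changes were recovered. Both simulations gave all genotypes the same spread per gene or family. In the data, Spearman correlations between libraries were 0.949 to 0.987 in set-25 and 0.997 to 0.998 in the double mutant. The simulated rates may therefore not hold for comparisons with these groups.

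Genes were also tested as 36 lists: heterochromatin, small RNA, repair, R-loop, apoptosis, germline, zygotic, tissue, stress, cell-cycle and dosage compensation genes, and gene families by symbol. Lists were compared with all other genes by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. fry, which asks whether the genes of a list changed at all and not against other genes, was run beside it. The shifted list in simulated data was called and 0 of 35 unshifted lists were. The simulated genes were drawn independently, so this does not test false calls among genes that vary together. Lists with fewer than 5 tested genes were not tested: mitochondrially encoded genes (not in the table), major sperm proteins (0) and ribosomal RNA genes (3). Counts within a list are also given adjusted over the list alone. Place on chromosomes was tested with Fisher's exact test, for which each autosome was divided into 3 equal parts by length, up to the last annotated gene end, and the outer parts were called arms. The share of counts in repeats was compared by exact permutation. Shared changes were set against 20 simulations with no change that share the N2 libraries.

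The genes and families named were set by a rule before the data were examined. It takes met-2 and set-25, then per comparison with N2 the 8 highest and 8 lowest log2 changes with a symbol and 2 of each without, among genes with adjusted p under 0.05, a change of at least 2-fold, at least 1 CPM on average and no overlap between the 3 mutant and 3 N2 libraries. By chance 10% of genes show no such overlap. It adds up to 4 members of each list past its test, 4 highest and 4 lowest in direct comparisons and the interaction, and 8 highest and 4 lowest repeat families; part of these are given. Where 5 or fewer genes of a list past its test were called in a direction they are named, part of them outside the rule and so chosen after their values were seen. Other names outside the rule are marked in the same way.

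Alternatives fixed before the data were examined were median-ratio size factors, no filter on low counts, DESeq2 1.42.0, a change of at least 2-fold, each library left out, only the libraries compared, TMM within the repeat table, genes and repeats in 1 table, another arm boundary and the repeat share without its largest family. For repeats DESeq2 used size factors from the gene table. Chosen after seeing the data were thinning to 16929810 counts per library, library totals without TMM, only the libraries compared for repeats, fits without the libraries labelled met-2, and the letter as a block. Other splits of the libraries were refitted with only the libraries compared, 10 splits per pair and 100 drawn for the interaction. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Other data types of the study were not used here.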

Results

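Total RNA depleted of ribosomal RNA was sequenced from early embryos of Caenorhabditis elegans grown at 20 °C. MET-2 and SET-25 are the histone methyltransferases that methylate lysine 9 of histone H3 (H3K9) in the worm. The comparisons ask which genes and repeat families change in RNA level when either enzyme, or both, is lost. There were 4 genotypes with 3 libraries each, called a, b and c here: wild type (N2), met-2(n4256), set-25(n5021) and the met-2 set-25 double mutant. The labels state 2 independent biological replicates and list 3 libraries per genotype, so part of the spread between libraries may be technical. The labels describe embryos of about 1 to 300 cells.

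Gene counts per library were 41033729 to 52683919 in N2 and 42943190 to 46833848 in the double mutant. They were 23543963 to 25667207 in the libraries labelled met-2 and 16929810 to 23924919 in set-25. The single mutants were thus sequenced less deeply than N2 and the double mutant. With every library thinned to 16929810 counts, 8080 and 5771 genes were called for the libraries labelled met-2 and for set-25 against N2, where 9236 and 6519 were called before. A batch that goes with depth cannot be told apart from genotype. Repeat families took 186996 to 622244 counts per library. Spearman correlations between libraries of the same genotype were 0.949 to 0.998 across genes, and the lowest was between set-25 libraries a and c. After TMM scaling the median log2 change of all tested genes against N2 was 0.05 for the libraries labelled met-2, 0.07 for set-25 and -0.01 for the double mutant. With library totals alone it was 0.32, 0.37 and 0.00, and changes below are relative to the TMM value. Against met-2 and set-25 the double mutant's median moved from -0.12 to -0.38 and from -0.10 to -0.39 with totals, and the interaction's from -0.19 to -0.76. Values are TMM-scaled counts per library in CPM, mean ± SD with n = 3, and SE is that of the log2 change. Intervals and lower bounds cover counting error only.

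Both mutated genes kept measurable RNA. met-2 (R05D3.11, chromosome III, 8375300 to 8380848) stood at 322 ± 7.91 CPM in N2 and 52.4 ± 1.65 CPM in the double mutant, a log2 change of -2.62 (SE 0.03, adjusted p = 5.00e-07). In the libraries labelled met-2 it stood at 267 ± 49.6 CPM, which is 215, 275 and 313 CPM in libraries a, b and c. That log2 change, -0.27 (SE 0.16, adjusted p = 0.0757), was not past the threshold. It became 0.00466 (adjusted p = 0.977) with library totals and -0.40 (adjusted p = 0.0128) without library c of this group. In set-25 the met-2 RNA stood at 329.8 ± 29.3 CPM, a log2 change of 0.04 (SE 0.08, adjusted p = 0.830); with library totals it was 0.34 (adjusted p = 0.0325), and with no filter on low counts the sign turned, to -0.0113. The RNA level of the libraries labelled met-2 therefore differs from that of the double mutant, which by its label carries the same allele. The log2 difference of the double mutant from it was -2.35 (SE 0.16, adjusted p = 5.98e-07), and every direction below for this group belongs to libraries so labelled.

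set-25 (Y43F4B.3, chromosome III, 13283824 to 13293090) stood at 195 ± 20.3 CPM in N2. It fell to 38.3 ± 1.52 CPM in the set-25 mutant, a log2 change of -2.35 (SE 0.09, adjusted p = 6.56e-07), and to 60.1 ± 2.41 CPM in the double mutant, -1.70 (SE 0.09, adjusted p = 6.15e-05). The double mutant held more of it than the single mutant, by a log2 difference of 0.65 (SE 0.05, adjusted p = 0.00311). The libraries labelled met-2 had 100.5 ± 20.4 CPM of set-25, a log2 change of -0.95 (SE 0.20, adjusted p = 1.00e-04).

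**Figure D1:**
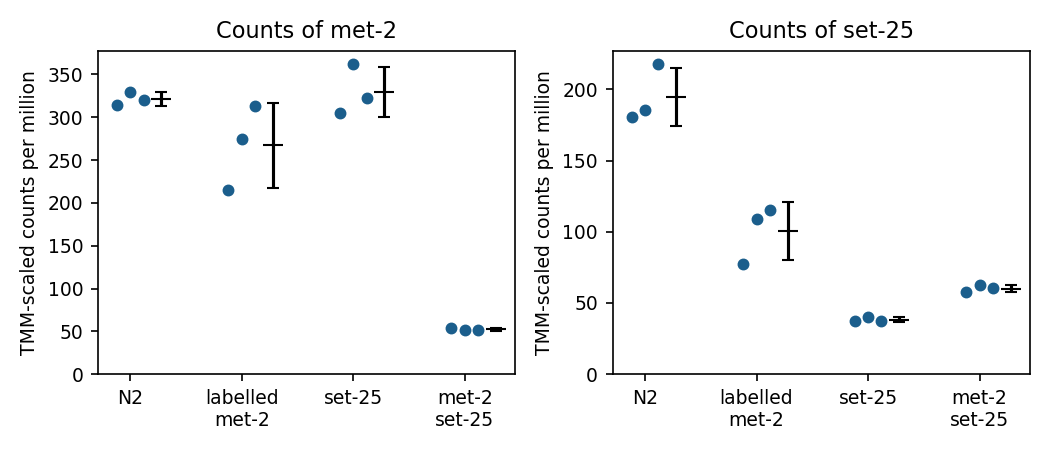
RNA of met-2 and set-25 in TMM-scaled CPM in each of the 12 libraries, by genotype, with points for libraries and bars for mean and SD. met-2 RNA lies at 52.4 CPM in the double mutant against 322 CPM in N2 and 267 CPM in the libraries labelled met-2, and set-25 RNA is lower than in N2 in all 3 mutant groups.

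The libraries labelled met-2 were compared with N2 to ask what loss of MET-2 does. Their RNA differed from that of N2 across much of the transcriptome. Lists of transcripts that mothers load into the embryo, of germline factors and of cell-cycle genes were lower. Lists of cuticle collagens and of muscle, gut and pharynx genes, which differentiating cells make, were higher. These list calls rest on a preset correlation between genes: with an estimated one camera called 0 of 36 lists (smallest adjusted p = 0.304, 3 lists at an unadjusted p under 0.05). fry, which tests a list against no change and not against other genes, called 27. Fitted with only the 6 libraries compared, camera with the preset correlation called 21 lists. Of the 10 splits of these libraries, 6 gave as many, the real one among them. The number of list calls is therefore no larger than other splits give. Of 14260 genes tested, 5017 rose and 4219 fell, and with library totals 6250 rose and 2440 fell. Depth differs between these groups, and the met-2 RNA leaves the label in doubt. A difference in embryo age may also explain part of these changes, which over all genes followed the difference between set-25 libraries c and a, of 1 genotype, with Spearman rho 0.686.

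Collagens were among the genes with large increases. The collagen col-74 rose from 0.1041 ± 0.0690 to 420.0 ± 187 CPM, a log2 change of 11.90 (SE 0.60, adjusted p = 1.40e-05). The collagens col-165, col-65 and col-14 rose by log2 values of 10.61 (SE 0.80), 9.54 (SE 0.57) and 9.16 (SE 0.55), and the cuticlin cut-3 by 9.23 (SE 0.44). Other genes named by the rule had 3 counts or fewer over the N2 group. Ratios with 95% counting intervals were 1400.4-fold (251 to 55315) for grl-5, 895-fold (306 to 4341) for col-125, 807-fold (224 to 6667) for ram-2 and 4513-fold (810.0 to 178262) for K01D12.9. F26G1.5 had no count in N2 and was at least 380.3-fold higher. Of 80 collagens, 55 rose and 2 fell (col-136 and col-176), or 55 and 2 adjusted over the list alone, with camera adjusted p = 9.41e-07, and adjusted p = 0.506 with an estimated correlation. At the other end wip-1, which encodes a WASP-interacting protein, fell from 47.2 ± 9.36 to 4.65 ± 1.91 CPM, a log2 change of -3.34 (SE 0.35, adjusted p = 3.84e-06). The small heat shock gene sip-1 of oocytes and embryos fell from 1904 ± 389 to 229.8 ± 17.9 CPM, -3.05 (SE 0.18, adjusted p = 2.04e-06). The germline stem cell gene sygl-1 changed by -3.001 (SE 0.17), fkb-2 by -2.88 (SE 0.13), the HMG-box gene hmg-1.1 by -2.84 (SE 0.10), Y39B6A.42 by -3.71 (SE 0.11) and W05F2.3 by -3.61 (SE 0.19).

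Germline and maternal lists were lower in the libraries labelled met-2. Of 25 maternal and oocyte transcripts, 22 fell (22 adjusted over the list alone), with camera adjusted p = 2.62e-14, and adjusted p = 0.436 with an estimated correlation. The RNA-binding genes pie-1, gld-1, mex-5 and oma-1 changed by log2 values of -2.29 (SE 0.21), -2.08 (SE 0.21), -2.06 (SE 0.20) and -1.87 (SE 0.15). Of 16 P granule components, 11 fell (11 adjusted over the list alone), with camera adjusted p = 0.00436, and adjusted p = 0.589 with an estimated correlation, and deps-1 changed by -1.57 (SE 0.12). Of 35 small RNA pathway genes, 19 fell (19 adjusted over the list alone), with camera adjusted p = 4.90e-04, and adjusted p = 0.506 with an estimated correlation; pid-1, alg-2 and the nuclear Argonaute hrde-1 changed by -1.75 (SE 0.16), -1.22 (SE 0.15) and -1.06 (SE 0.12). Of 24 H3K9 methylation and heterochromatin factors, 2 rose (set-11 and set-20) and 11 fell, or 2 and 10 adjusted over the list alone, with camera adjusted p = 0.00653, and adjusted p = 0.436 with an estimated correlation. Among these the chromodomain gene mrg-1 and the HP1 homolog hpl-1 changed by -1.67 (SE 0.11) and -1.29 (SE 0.09). Of 27 early zygotic genes, 23 fell (23 adjusted over the list alone), with camera adjusted p = 5.29e-06, and adjusted p = 0.506 with an estimated correlation, and the forkhead gene pes-1 changed by -1.72 (SE 0.19). Of 15 T-box genes, 13 fell (13 adjusted over the list alone), with camera adjusted p = 5.60e-05, and adjusted p = 0.436 with an estimated correlation, and tbx-38 changed by -1.70 (SE 0.18).

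Lists of division, chromatin and genome repair genes were called lower in this group too. Of 40 mitosis and cell-cycle genes, 33 fell (34 adjusted over the list alone), with camera adjusted p = 3.06e-08, and adjusted p = 0.436 with an estimated correlation. The PCNA gene pcn-1, the cyclin B gene cyb-3 and the replication helicase gene mcm-7 changed by -1.94 (SE 0.19), -1.78 (SE 0.25) and -1.32 (SE 0.17). Of 35 histone genes, 29 fell (29 adjusted over the list alone), with camera adjusted p = 1.41e-17, and adjusted p = 0.304 with an estimated correlation; his-74 and his-62 changed by -2.84 (SE 0.12) and -2.78 (SE 0.07). Histone genes share near-identical sequence, and how reads that fit several places were counted is not given in the sources used here. Of 75 cytosolic ribosomal protein genes, 2 rose (rpl-27 and rps-21) and 40 fell, or 2 and 40 adjusted over the list alone, with camera adjusted p = 3.25e-06, and adjusted p = 0.436 with an estimated correlation. For 45 genes of double-strand break repair and replication stress, 2 rose (rfs-1 and atl-1) and 20 fell, or 1 and 19 adjusted over the list alone, with camera adjusted p = 0.00653, and adjusted p = 0.601 with an estimated correlation; their median of -0.24 became 0.03 with library totals. The checkpoint gene mrt-2 and the BRCA1 homolog brc-1 changed by -1.15 (SE 0.11) and -0.86 (SE 0.11). Of 14 R-loop processing genes, 1 rose (rnh-1.3) and 9 fell, or 1 and 9 adjusted over the list alone, with camera adjusted p = 0.0450, and adjusted p = 0.589 with an estimated correlation, and aly-2 changed by -1.02 (SE 0.19). Among 21 apoptosis genes, 5 rose (nuc-1, cps-6, ced-7, ced-8 and ced-1) and 10 fell, or 5 and 10 adjusted over the list alone, with camera adjusted p = 0.0367, and adjusted p = 0.436 with an estimated correlation, and the median of -0.23 became 0.04 with totals. The BH3-only gene egl-1 and the caspase gene ced-3 changed by -2.19 (SE 0.37) and -1.43 (SE 0.08). Of 269 F-box genes, 37 rose, 128 were not called and the others fell (33 and 97 rose and fell adjusted over the list alone), with camera adjusted p = 0.00735, and adjusted p = 0.660 with an estimated correlation. Among 54 homeobox genes, 11 rose and 24 fell (11 and 24 adjusted over the list alone), with camera adjusted p = 0.0327, and adjusted p = 0.436 with an estimated correlation. There the test pointed down with a median of -0.21, 0.06 with totals, while the mean was 0.10; ceh-18 rose by 4.46 (SE 0.41).

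Lists of muscle, pharynx, intestine and response genes were higher in the libraries labelled met-2. Of 20 body wall muscle genes, 16 rose and 1 fell (hlh-1), or 16 and 1 adjusted over the list alone, with camera adjusted p = 0.00436, and adjusted p = 0.608 with an estimated correlation. The giant muscle proteins unc-22 and ttn-1 rose by log2 values of 3.88 (SE 0.45) and 3.78 (SE 0.62). Of 12 pharynx genes, 8 rose and 2 fell (pha-4 and gst-20), or 8 and 2 adjusted over the list alone, with camera adjusted p = 0.00917, and adjusted p = 0.589 with an estimated correlation, and the pharyngeal myosins myo-1 and myo-2 rose by 7.28 (SE 0.44) and 5.88 (SE 0.44). Of 16 intestine genes, 11 rose and 3 fell (elt-7, elt-2 and end-1), or 11 and 3 adjusted over the list alone, with camera adjusted p = 0.0367, and adjusted p = 0.589 with an estimated correlation, and the protease gene asp-1 rose by 6.96 (SE 0.48). Of 65 neuropeptide genes, 45 rose and 6 fell (45 and 6 adjusted over the list alone), with camera adjusted p = 1.47e-04, and adjusted p = 0.589 with an estimated correlation. Of 16 pathogen response genes, 8 rose (8 adjusted over the list alone), with camera adjusted p = 0.0369, and adjusted p = 0.506 with an estimated correlation, and the lysozyme lys-1 rose by 5.17 (SE 0.40). Of 83 C-type lectins, 46 rose and 7 fell (46 and 7 adjusted over the list alone), with camera adjusted p = 6.79e-04, and adjusted p = 0.535 with an estimated correlation, and clec-63 rose by 6.50 (SE 0.41). Of 52 cytochrome P450 genes, 38 rose and 2 fell (cyp-31A5 and cyp-44A1), or 39 and 2 adjusted over the list alone, with camera adjusted p = 2.32e-06, and adjusted p = 0.436 with an estimated correlation, and cyp-35A3 rose by 6.59 (SE 0.43). Of 58 UDP-glucuronosyltransferase genes, 44 rose and 1 fell (ugt-38), or 44 and 1 adjusted over the list alone, with camera adjusted p = 5.72e-06, and adjusted p = 0.436 with an estimated correlation. Of 207 nuclear hormone receptor genes, 85 rose and 19 fell (84 and 18 adjusted over the list alone), with camera adjusted p = 0.0327, and adjusted p = 0.801 with an estimated correlation. The 27 neuron genes and the 22 epidermis genes did not pass this test, with camera adjusted p = 0.189 and 0.643.

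The set-25 mutant was compared with N2 to ask what loss of SET-25 does. Lists of maternal, cell-cycle, histone and ribosomal protein genes were lower, and those of collagens, pharynx and several response families were higher. With an estimated correlation camera called 0 of 36 lists here (smallest adjusted p = 0.440, 3 at an unadjusted p under 0.05), and fry called 21. Here 5 of the 10 splits of the 6 libraries gave as many list calls as the real one, which is among the 5. Whether lists differ between the single mutants was not tested. Of 14260 genes, 3445 rose and 3074 fell, and with library totals 5778 rose and 1762 fell. The set-25 libraries spread widely, with an SD near the mean for the collagens, and depth differs from N2. Fitted with only these 6 libraries, 1868 genes rose and 2175 fell, and without set-25 library c 1911 genes fell.

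Here too collagens were among the genes with large increases. col-74 rose to 163 ± 143 CPM, a log2 change of 10.53 (SE 1.33, adjusted p = 3.65e-05), and col-165, col-65, col-14 and cut-3 rose by 9.32 (SE 1.32), 7.90 (SE 1.12), 7.67 (SE 1.19) and 7.58 (SE 0.95). Genes with 3 counts or fewer in N2 gave ratios of 471-fold (84.5 to 18590.1) for grl-5, 169-fold (57.7 to 817) for col-125 and 1918-fold (344 to 75743) for K01D12.9. fip-6 and F26G1.5 had no count in N2 and were at least 79.3-fold and at least 135-fold higher. wip-1 fell to 4.23 ± 0.830 CPM, a log2 change of -3.48 (SE 0.24, adjusted p = 3.46e-06). sygl-1 changed by -3.37 (SE 0.36), yop-1 by -3.12 (SE 0.21), sdz-20 by -3.06 (SE 0.17), sip-1 by -2.95 (SE 0.30), the Pumilio-family gene puf-7 by -2.83 (SE 0.28), Y39B6A.42 by -3.79 (SE 0.30) and ZK546.18 by -3.83 (SE 1.02). Of 80 collagens, 39 rose and 3 fell (col-99, col-155 and col-176), or 39 and 3 adjusted over the list alone, with camera adjusted p = 2.51e-05, and adjusted p = 0.689 with an estimated correlation.

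Among the lower lists in set-25, 25 maternal and oocyte transcripts gave camera adjusted p = 5.96e-18, and adjusted p = 0.473 with an estimated correlation. Of these 21 fell (21 adjusted over the list alone), and pie-1, mex-5 and gld-1 changed by -2.28 (SE 0.24), -2.28 (SE 0.27) and -2.18 (SE 0.26). For P granule components 6 fell (6 adjusted over the list alone), with camera adjusted p = 0.0419, and adjusted p = 0.690 with an estimated correlation; the median of -0.20 became 0.11 with totals. For small RNA pathway genes 1 rose (nrde-1) and 13 fell, or 1 and 13 adjusted over the list alone, with camera adjusted p = 0.0129, and adjusted p = 0.689 with an estimated correlation; the median of -0.21 became 0.09 with totals, and alg-2 changed by -1.40 (SE 0.23). Of the early zygotic genes 15 fell (1 rose and 19 fell adjusted over the list alone), with camera adjusted p = 0.00119, and adjusted p = 0.689 with an estimated correlation. Of the T-box genes 10 fell (11 adjusted over the list alone), with camera adjusted p = 5.14e-04, and adjusted p = 0.689 with an estimated correlation. Of the mitosis and cell-cycle genes 1 rose (mdf-1) and 22 fell, or 1 and 22 adjusted over the list alone, with camera adjusted p = 1.44e-05, and adjusted p = 0.689 with an estimated correlation, and pcn-1 changed by -1.71 (SE 0.15). Histone genes gave camera adjusted p = 5.12e-14, and adjusted p = 0.440 with an estimated correlation, and 1 rose (his-37) and 23 fell, or 1 and 24 adjusted over the list alone. Ribosomal protein genes gave camera adjusted p = 8.54e-06, and adjusted p = 0.473 with an estimated correlation, and 5 rose (rpl-23, rpl-22, rpl-27, rps-21 and rpl-32) and 39 fell, or 6 and 39 adjusted over the list alone, with rpl-20 at -1.95 (SE 0.18). Of the homeobox genes 9 rose and 21 fell (9 and 21 adjusted over the list alone), with camera adjusted p = 0.0355, and adjusted p = 0.689 with an estimated correlation, and their median of -0.22 became 0.08 with totals. Of 22 epidermis genes 4 rose (dpy-7, dpy-17, dpy-2 and dpy-10) and 9 fell, or 4 and 10 adjusted over the list alone, with camera adjusted p = 0.0249, and adjusted p = 0.690 with an estimated correlation; let-653, elt-3, nhr-23 and lin-26 changed by -1.38 (SE 0.25), -1.29 (SE 0.30), -1.18 (SE 0.21) and -1.16 (SE 0.09).

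Among the higher lists in set-25, the pharynx genes gave camera adjusted p = 0.0249, and adjusted p = 0.690 with an estimated correlation. Of these 8 rose and 1 fell (pha-4), or 8 and 1 adjusted over the list alone, and myo-1 rose by 5.33 (SE 1.32). Pathogen response genes gave camera adjusted p = 0.0145, and adjusted p = 0.689 with an estimated correlation, and 5 rose (nlp-29, pals-22, cnc-4, lys-1 and lys-2), or 5 adjusted over the list alone. Neuropeptide genes gave camera adjusted p = 0.0419, and adjusted p = 0.690 with an estimated correlation, and 21 rose and 7 fell (21 and 7 adjusted over the list alone). C-type lectins gave camera adjusted p = 0.00884, and adjusted p = 0.689 with an estimated correlation, and 35 rose and 10 fell (36 and 10 adjusted over the list alone). Cytochrome P450 genes gave camera adjusted p = 2.61e-04, and adjusted p = 0.689 with an estimated correlation, and 24 rose and 1 fell (cyp-31A5), or 24 and 1 adjusted over the list alone, with cyp-35A3 at 5.22 (SE 0.51). UDP-glucuronosyltransferase genes gave camera adjusted p = 0.0103, and adjusted p = 0.689 with an estimated correlation, and 21 rose and 3 fell (ugt-46, ugt-37 and ugt-34), or 20 and 2 adjusted over the list alone. Nuclear hormone receptor genes gave camera adjusted p = 0.0249, and adjusted p = 0.720 with an estimated correlation, and 63 rose and 24 fell (62 and 22 adjusted over the list alone). Lists that did not pass this test were muscle, intestine and neurons, with camera adjusted p = 0.0802, 0.150 and 0.686. The same held for heterochromatin factors, repair, R-loop, apoptosis and F-box genes, with 0.117, 0.208, 0.906, 0.0877 and 0.350.

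The double mutant was compared with N2 to ask what follows when both enzymes are lost. In the fit of all 12 libraries it differed from N2 in fewer genes than either single mutant, at a depth like that of N2. Some collagens, 2 cuticlin genes and a chemoreceptor were higher, F-box genes went both ways, with the list called lower only under the preset correlation (camera adjusted p = 0.00263, and 0.808 with an estimated one), and single genes such as plk-3 and ztf-15 were sharply lower. Of 14260 genes, 1241 rose and 476 fell; with median-ratio size factors 1446 rose and 271 fell. The count fell when any library was left out: 368, 777 and 402 genes were called without N2 libraries a, b and c, and 493, 557 and 565 without double-mutant libraries a, b and c. With only the 6 libraries compared, 3139 rose and 2975 fell, more than for set-25 in the same kind of fit, and 1660 of the 1717 were called in both fits in the same direction. Fewer genes were called with the letter as a replicate block, and more with DESeq2 (2118 higher and 573 lower). Of lists, camera called 0 with an estimated correlation (smallest adjusted p = 0.808, 0 at an unadjusted p under 0.05). With fry 1 list was called, spermatogenesis, as higher (fry adjusted p = 0.0299). Camera did not call that list (adjusted p = 0.165), and fry called none of the lists described below for this group. As for set-25, 5 of the 10 splits of the 6 libraries gave as many list calls as the real one, which is among the 5. Embryo age may explain part of the double mutant's changes too. Over all genes they followed the difference between set-25 libraries c and a with Spearman rho 0.686.

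Some genes stayed past the threshold whichever single library was left out. The polo-like kinase gene plk-3 (chromosome IV, 7470860 to 7473209) fell from 28.2 ± 0.791 to 1.099 ± 0.154 CPM, a log2 change of -4.67 (SE 0.11, adjusted p = 1.24e-07). Its neighbour slc-25A18.2 (7475041 to 7476182) changed by -1.93 (SE 0.18, adjusted p = 0.00164). The zinc finger gene ztf-15 fell from 37.5 ± 3.59 to 2.50 ± 0.129 CPM, -3.91 (SE 0.09, adjusted p = 1.24e-07). Other decreases were hint-3 at -3.47 (SE 0.18), Y11D7A.7 at -3.22 (SE 0.09), fbxa-107 at -1.96 (SE 0.08), the mitochondrial thioredoxin trx-2 at -1.75 (SE 0.11) and the thiamine pyrophosphokinase tpk-1 at -1.73 (SE 0.22). The chemoreceptor srw-85 rose from 0.0448 ± 0.0556 to 6.75 ± 0.316 CPM, 7.22 (SE 0.43, adjusted p = 0.00715), and stood at 1.12 ± 1.81 in the libraries labelled met-2. col-74 rose to 20.04 ± 2.85 CPM, 7.51 (SE 0.42, adjusted p = 0.00343), and col-165, cut-2 and cut-3 by 6.41 (SE 0.69), 5.99 (SE 0.50) and 5.15 (SE 0.30). The cuticle-related genes grl-7 and grl-15 rose by 5.01 (SE 0.63) and 4.74 (SE 0.55), pqn-32 by 4.63 (SE 0.15), C50D2.1 by 6.10 (SE 0.19) and F41F3.3 by 5.76 (SE 0.93).

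Lists called higher in the double mutant follow. For collagens 8 rose (14 rose and 2 fell adjusted over the list alone), with camera adjusted p = 0.0162, and adjusted p = 0.851 with an estimated correlation. Of the C-type lectins 16 rose and 2 fell (clec-252 and clec-171), or 27 and 6 adjusted over the list alone, with camera adjusted p = 0.0125, and adjusted p = 0.808 with an estimated correlation; clec-180 rose by 3.01 (SE 0.52), and clec-26 gave a ratio of 19.4-fold (6.62 to 93.9). For nuclear hormone receptors 9 rose and 2 fell (nhr-10 and nhr-95), or 0 and 0 adjusted over the list alone, with camera adjusted p = 0.0477, and adjusted p = 0.871 with an estimated correlation. Body wall muscle gave camera adjusted p = 2.66e-05, and adjusted p = 0.808 with an estimated correlation, and 9 rose (14 adjusted over the list alone). ttn-1 rose by 2.40 (SE 0.49), a call lost without N2 library a (0.0664) or c (0.0800) and without double-mutant library a (0.0618), b (0.0588) or c (0.0558), with adjusted p in parentheses. Neuron genes gave camera adjusted p = 0.0125, and adjusted p = 0.808 with an estimated correlation, and 4 rose (rab-3, egl-21, sad-1 and unc-13), or 5 adjusted over the list alone. In each of the 6 fits without 1 library the calls of egl-21 (adjusted p = 0.0525 to 0.109), sad-1 (0.0754 to 0.156) and rab-3 (0.0763 to 0.155) were lost. unc-13 rose by 2.52 (SE 0.37), a call lost without N2 library a (adjusted p = 0.0591) or c (adjusted p = 0.0667). Pharynx genes gave camera adjusted p = 0.00208, and adjusted p = 0.808 with an estimated correlation, and 4 rose (pqn-8, myo-1, peb-1 and tni-4), or 5 adjusted over the list alone; pqn-8 rose by 2.52 (SE 0.15), lost without N2 library a (adjusted p = 0.0602). Epidermis genes gave camera adjusted p = 0.00839, and adjusted p = 0.808 with an estimated correlation, and 2 rose (dpy-3 and sqt-3), or 3 adjusted over the list alone. The calls of sqt-3 (adjusted p = 0.0821 to 0.163), dpy-3 (0.0686 to 0.152), myo-1 (0.0566 to 0.0924) and peb-1 (0.0720 to 0.137) were lost in each fit without 1 library. tni-4 lost its call without N2 library a (adjusted p = 0.0631) or c (0.0744) and without double-mutant library c (0.0503).

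Lists called lower in the double mutant, F-box genes apart, held at most 4 called genes. F-box genes gave camera adjusted p = 0.00263, and adjusted p = 0.808 with an estimated correlation. Of these 15 rose and 22 fell (15 and 22 adjusted over the list alone), with a median of -0.23, and the strongest were increases: fbxa-43 rose by 4.47 (SE 0.29) and fbxa-136 by 2.77 (SE 0.18). Histone genes gave camera adjusted p = 2.66e-05, and adjusted p = 0.808 with an estimated correlation, and 4 fell (his-41, his-37, his-71 and his-59), or 4 adjusted over the list alone. his-59 changed by -0.56 (SE 0.11), a call lost without any 1 of the 6 libraries compared, with adjusted p = 0.114, 0.0578 and 0.0811 without N2 libraries a, b and c, and 0.118, 0.0749 and 0.126 without those of the double mutant. Maternal and oocyte transcripts gave camera adjusted p = 0.00208, and adjusted p = 0.808 with an estimated correlation, and 2 fell (egg-1 and chs-1), or 1 adjusted over the list alone. Repair and replication stress genes gave camera adjusted p = 5.85e-04, and adjusted p = 0.808 with an estimated correlation, and 2 fell (rtel-1 and rev-3), or 0 adjusted over the list alone. R-loop genes gave camera adjusted p = 0.0111, and adjusted p = 0.808 with an estimated correlation, and 1 fell (rnh-2), or 1 adjusted over the list alone. Early zygotic genes gave camera adjusted p = 2.66e-05, and adjusted p = 0.808 with an estimated correlation, and 1 fell (vet-1), or 0 adjusted over the list alone. Lost in each of the 6 fits were his-41 (adjusted p = 0.0524 to 0.128), his-71 (0.0530 to 0.149), his-37 (0.0710 to 0.150), egg-1 (0.0844 to 0.193), rtel-1 (0.117 to 0.167), rev-3 (0.0767 to 0.127) and vet-1 (0.0639 to 0.143). chs-1 lost its call without N2 library c (adjusted p = 0.0602) and without double-mutant library a (0.0651) or c (0.0566), and rnh-2 without N2 library a (adjusted p = 0.0869) or c (0.0810) and without double-mutant library a (0.0824), b (0.0705) or c (0.0866). Mitosis genes gave camera adjusted p = 0.00839, and adjusted p = 0.808 with an estimated correlation, and T-box genes gave camera adjusted p = 0.0125, and adjusted p = 0.808 with an estimated correlation, with no gene called in either. Heterochromatin factors, small RNA, P granule, apoptosis, intestine and pathogen response genes did not pass this test, with camera adjusted p = 0.730, 0.977, 0.425, 0.0954, 0.0902 and 0.389. Nor did P450, UDP-glucuronosyltransferase, ribosomal protein, neuropeptide and homeobox genes, with 0.213, 0.606, 0.369, 0.588 and 0.726.

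**Figure D2:**
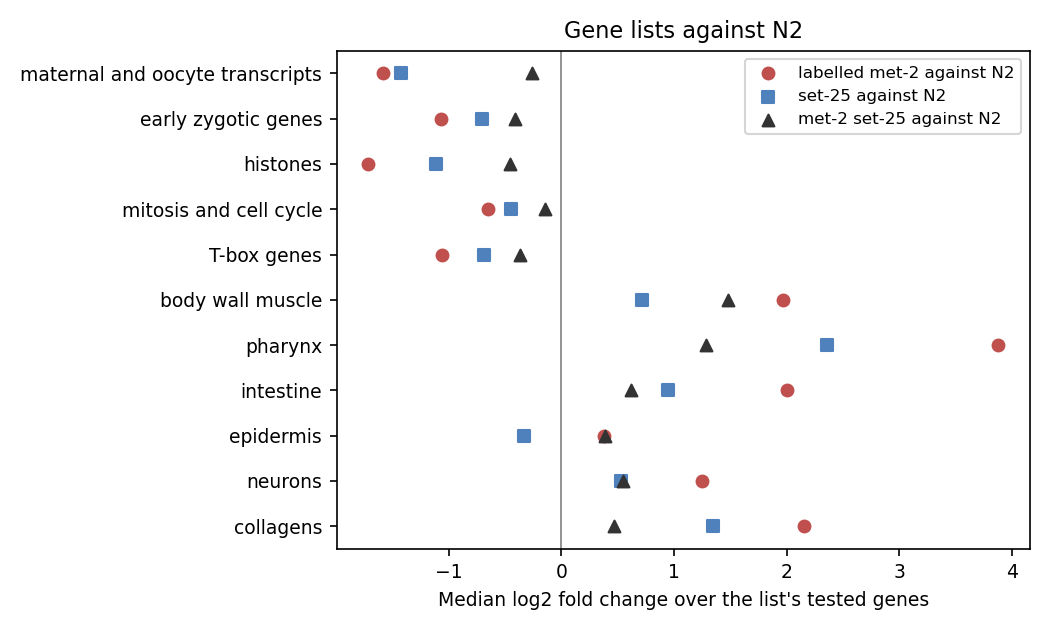
Median log2 change against N2 over the tested genes of 11 lists, with a circle for the libraries labelled met-2, a square for set-25 and a triangle for the double mutant. Maternal, zygotic, histone, mitosis and T-box medians lie below 0 in all 3 groups under TMM, median-ratio and total scaling, and the medians of the other lists lie above 0 except epidermis in set-25.

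Repeat families were compared because H3K9 methylation marks repeats in the worm. The double mutant showed a small set of increases, among them a DNA transposon and LTR retrotransposons. Simple repeats were 14 of the 26 families called there, 31 of 114 in the libraries labelled met-2 and 20 of 50 in set-25. Simple repeats inside genes cannot be told from the transcripts of those genes. Of 257 families tested, 22 rose and 4 fell in the double mutant, and with only the 6 libraries compared 33 rose and 28 fell.

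CEMUDR1, a MuDR-like DNA transposon, rose from 82.1 ± 0.942 CPM in N2 to 342 ± 11.6 CPM in the double mutant, a log2 change of 2.06 (SE 0.03, adjusted p = 1.51e-06). It stood at 136 ± 9.17 CPM in set-25 and 98.1 ± 29.4 CPM in the libraries labelled met-2. The internal part of the LTR retrotransposon CER10, CER10-I_CE, rose from 1.45 ± 0.152 to 9.83 ± 0.643 CPM, 2.76 (SE 0.10, adjusted p = 1.61e-05). The DNA transposon Turmoil1 and the LTR element CER3-I_CE rose by 1.87 (SE 0.23) and 1.81 (SE 0.15). The simple repeats (GAATG)n, (GATTG)n, (CATTC)n and (CGGGA)n rose by 1.86 (SE 0.15), 1.75 (SE 0.27), 1.74 (SE 0.13) and 1.73 (SE 0.08). Each of these 8 stayed past the threshold whichever library was left out. Each of the 4 lower families was lost in some such fits. CER3-LTR_CE changed by -1.25 (SE 0.26), lost without N2 library a (adjusted p = 0.0525) and without double-mutant library a (0.0943) or c (0.0536). CER16-I_CE changed by -1.22 (SE 0.23), lost without N2 library a (adjusted p = 0.1036) or c (0.116) and without double-mutant library a (0.202), b (0.0693) or c (0.122). CER11-I_CE changed by -1.60 (SE 0.31), lost without N2 library a (adjusted p = 0.0807) or c (0.130) and without double-mutant library a (0.186), b (0.136) or c (0.0560). (CTAGT)n changed by -2.71 (SE 0.74), lost without N2 library c (adjusted p = 0.110) and without double-mutant library a (0.0902), b (0.0606) or c (0.0536). The 2 families classed as satellites by name were not called in any comparison with N2. They are named after their values were seen because the study's title names satellite repeats. In the double mutant MINISAT1_CE changed by -0.08 (SE 0.08, adjusted p = 0.859) and MSAT1_CE by -0.45 (SE 0.26, adjusted p = 0.321). In the libraries labelled met-2 they changed by 0.31 (SE 0.12, adjusted p = 0.147) and 0.53 (SE 0.34, adjusted p = 0.0955), and in set-25 by -0.31 (SE 0.24, adjusted p = 0.235) and 0.04 (SE 0.28, adjusted p = 0.930). Families were classed by name alone, so these 2 do not stand for all satellite repeats. Tandem repeats such as (GAATG)n are counted among the simple repeats. Of 35 LTR families 6 rose and 3 fell, of 58 DNA transposon families 3 rose (CEMUDR1, Turmoil1 and CEMUDR2, the last named after its value was seen), and of 82 simple repeats 13 rose and 1 fell.

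In set-25, 12 families rose and 38 fell, 30 and 31 with TMM within the repeat table, 25 and 23 with totals, and 27 and 34 with genes and repeats scaled together. CER3-I_CE and CER10-I_CE rose by 1.76 (SE 0.19) and 1.73 (SE 0.29), as in the double mutant, and without set-25 library a or b 21 and 22 families rose. The DNA transposon TIR43YW1_CE rose by 1.198 (SE 0.34). (TAG)n rose by 2.59 (SE 0.31), and (CAG)n and (GGGAA)n changed by -2.99 (SE 0.20) and -3.32 (SE 0.37). In the libraries labelled met-2, 89 families rose and 25 fell, 139 and 17 with totals, but 44 and 47 with TMM within the repeat table, so the lean to increases rests on the scaling. Without N2 library b or c, 75 and 72 families were called. (TAG)n and the polypurine family rose by 4.29 (SE 0.87) and 2.80 (SE 0.24), and (CAG)n, (TC)n and (GGGAA)n changed by -2.46 (SE 0.29), -2.22 (SE 0.30) and -2.71 (SE 0.40). CELE45 alone held 46.1 to 54.5% of repeat counts in N2 libraries; it stood at 6698 ± 1224 CPM in N2, 2008 ± 844 in the libraries labelled met-2, 4488 ± 1180.3 in set-25 and 5838 ± 488 in the double mutant.

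Repeat families together took 1.22 ± 0.0984% of counts in N2 and 1.14 ± 0.0543% in the double mutant, a difference of -0.0753 (exact permutation p = 0.4, testing both directions). They took 1.06 ± 0.0791% in the libraries labelled met-2, a difference of -0.155 (exact p = 0.1), and 1.12 ± 0.0323% in set-25, -0.100 (exact p = 0.2). The smallest p that 3 against 3 libraries allow is 0.1. Without N2 library b the differences shrank to -0.0188 in the double mutant, -0.0982 in the libraries labelled met-2 and -0.0435 in set-25. Without CELE45 the differences were -0.00273 in the double mutant, 0.225 in the libraries labelled met-2 and 0.00297 in set-25, so both single-mutant signs turn with that family.

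**Figure D3:**
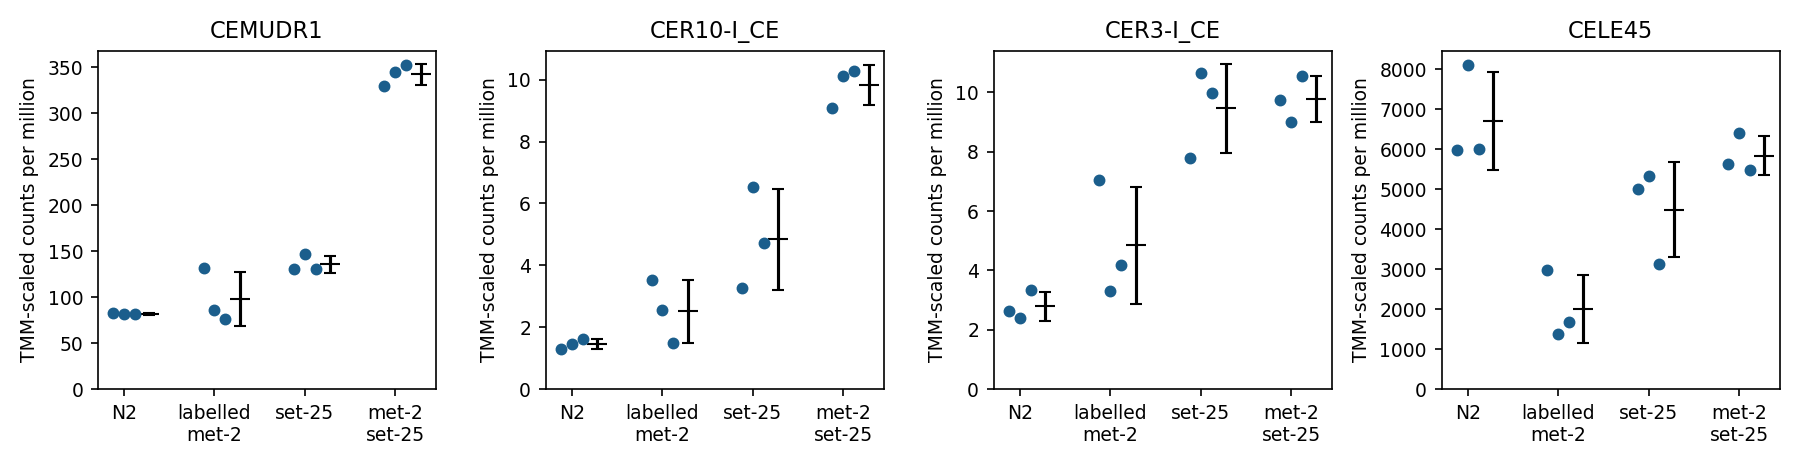
RNA of 4 repeat families in TMM-scaled CPM in each library, by genotype, with points for libraries and bars for mean and SD. CEMUDR1 stands at 342 CPM in the double mutant against 82.1 CPM in N2, and CELE45 is the family with the most counts.

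The double mutant was set against each single mutant, and the single mutants against each other, to ask what the further mutation changes. wip-1, low in both single mutants, was higher in the double mutant than in either, and the collagen col-77 was lower. Depth differs between the double mutant and both single mutants.

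Against the libraries labelled met-2, 3300 genes rose and 4396 fell, 1959 and 6064 with totals. The doublesex-family gene dmd-9 rose by 3.49 (SE 0.28), wip-1 by 3.31 (SE 0.32), fbxa-43 by 3.13 (SE 0.71) and hmg-1.1 by 2.93 (SE 0.06). col-77 and col-125 changed by -9.19 (SE 0.64) and -7.21 (SE 0.56), while lips-6 and idpc-7, with 1 count each in the double mutant, gave ratios of 256-fold (45.9 to 10108) and 256-fold (45.9 to 10108). Against set-25, 2918 genes rose and 2530 fell, 1818 and 5065 with totals. Without double-mutant libraries a, b and c 1301, 1296 and 1128 genes fell against set-25. srw-85 rose by 5.40 (SE 0.27), the arrestin-domain gene arrd-22 by 3.80 (SE 0.21), wip-1 by 3.45 (SE 0.19) and mihp-1 by 3.23 (SE 0.31). col-77 and col-115 changed by -6.93 (SE 1.16) and -4.93 (SE 1.23), and fip-6 and col-182 gave ratios of 121-fold (33.5 to 998) and 81.2-fold (27.8 to 394). Of the repeat families 34 rose and 91 fell against met-2 and 50 rose and 11 fell against set-25. These became 68 and 54, and 53 and 37, with TMM within the repeat table, 21 and 134, and 37 and 55, with totals, and 50 and 26 against set-25 with genes and repeats scaled together. Without double-mutant library c, 82 families were called against met-2. The 11 decreases against set-25 became 4, 5 and 4 without double-mutant libraries a, b and c, and 20 and 18 without set-25 libraries a and b.

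Between the libraries labelled met-2 and set-25, 2205 genes were higher in the former and 1324 lower, but this count is unstable. Without met-2 libraries a, b and c it was 1389, 88 and 5421, and without set-25 libraries a and c 2182 and 6785, against 3529 with all; without set-25 library b 988 were higher. Fitted with these 6 libraries alone, 3 genes were called, all lower in the libraries labelled met-2: K10D3.6 at -2.86 (adjusted p = 0.00808), T03F1.6 at -2.14 (adjusted p = 0.00808) and eppl-1 at -2.83 (adjusted p = 3.73e-04), of which K10D3.6 and T03F1.6 are named after their values were seen. The mutated gene set-25 was not among them. Its RNA stood at 100.5 ± 20.4 CPM in the libraries labelled met-2 and 38.3 ± 1.52 CPM in set-25, with no overlap between libraries. In the fit of all 12 libraries that log2 difference was 1.39 (SE 0.18, adjusted p = 6.81e-04). The few calls with 6 libraries therefore do not show that few genes differ. eppl-1 stood at 164 ± 23.9 CPM in set-25, 24.7 ± 2.28 in the libraries labelled met-2, 16.01 ± 0.264 in N2 and 13.3 ± 0.525 in the double mutant, a log2 difference of -2.74 (SE 0.14, adjusted p = 3.12e-07). ins-13, an insulin-like gene, was higher in the libraries labelled met-2 by 2.70 (SE 0.18, adjusted p = 2.81e-04). catp-3 and grd-14 were higher by 3.79 (SE 0.89) and 3.40 (SE 0.89) and fbxa-107 lower at -1.44 (SE 0.26), calls lost without met-2 library b (adjusted p = 0.0566, 0.0743 and 0.0566). With these 6 libraries alone ins-13 (adjusted p = 0.0882), catp-3 (0.113), grd-14 (0.113) and fbxa-107 (0.113) were not called. Of the repeat families 107 were higher and 8 lower in the libraries labelled met-2. With totals 99 were higher and 8 lower, and with genes and repeats scaled together 75 and 9. The count fell to 11 higher and 1 lower with only these 6 libraries, and to 75 in all without met-2 library b. The split was 5 and 12 with TMM within the repeat table. That scaling removes a shift shared by the families, so it cannot test the direction.

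An interaction term asked whether the double mutant departs from the sum of the single mutants' changes on the log2 scale. It was past the threshold for 3955 genes above that sum and 5166 below, 2299 and 7424 with totals, and for 40 and 55 repeat families, 28 and 132 with totals and 35 and 79 with genes and repeats scaled together. wip-1 and sip-1 lay above by 6.79 (SE 0.40, adjusted p = 8.55e-08) and 5.66 (SE 0.33, adjusted p = 7.24e-08), and col-77 below, at -16.09 (SE 1.34, adjusted p = 4.05e-06). This contrast sets N2 and the double mutant against the single mutants, as depth does. After thinning it was past the threshold for 7992 genes and 94 families. The 55 families below the sum became 33 and 34 without N2 libraries b and c, 31 and 30 without double-mutant libraries a and c, and 91 without set-25 library a.

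Shared changes were counted across the comparisons with N2. The libraries labelled met-2 and set-25 shared 3012 increases and 2537 decreases, against 1212 and 909 for independent lists, among them col-74 and wip-1. The libraries labelled met-2 and the double mutant shared 1015 and 261, against 437 and 141, and set-25 and the double mutant 887 and 107, against 300 and 103. All 3 comparisons shared 860 increases, col-74 among them, and 99 decreases. Changes in opposite directions numbered 30, 49 and 70 in the 3 pairs. Shared N2 libraries alone make such changes correlate across genes, which are not independent replicates: r was 0.932, 0.734 and 0.699, against 0.418, 0.468 and 0.451 in simulated data without changes. Among repeat families r was 0.726, 0.211 and 0.123 against 0.475, 0.498 and 0.529, and the covariance differed from the simulated one by 0.510, 0.0335 and -0.0106. The pairs shared 9, 15 and 7 family increases against 4.16, 7.62 and 1.03 for independent lists, with 0, 0 and 0.05 in simulated data, and 19, 1 and 1 decreases against 3.70, 0.389 and 0.591.

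Chromosome arms carry most H3K9 methylation in the worm, so the place of higher genes was tested. Among genes higher in the double mutant 63.4% lay in the outer parts of autosomes I to V, against 59.1% of the other tested genes there. The odds ratio was 1.2 (95% interval 1.046 to 1.38, Fisher's exact p = 0.00837), and it was 1.11 (Fisher's exact p = 0.140) for genes changed at least 2-fold. In the single mutants higher genes lay less often on the arms. The odds ratio was 0.783 (0.724 to 0.847, Fisher's exact p = 8.54e-10) in the libraries labelled met-2 and 0.697 (0.640 to 0.760, Fisher's exact p = 2.02e-16) in set-25. Lower genes gave 1.03 (Fisher's exact p = 0.482), 1.21 (Fisher's exact p = 2.87e-05) and 0.679 (Fisher's exact p = 7.80e-05) in the libraries labelled met-2, set-25 and the double mutant. Genes in clusters are not independent, and these p values do not allow for it.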

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

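Tests of the interaction, of shared changes and of chromosome arms were set before their results were seen; the tests of the met-2 label, of the interaction after thinning, of shared genes with only the libraries compared and of other splits of the libraries were chosen after.

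The double mutant's change differed from the sum of the single mutants' changes, by an interaction term, for 9121 genes and 95 repeat families. Among 100 splits of the 12 libraries only the real one gave as many, 1 of 100 for genes and 1 of 100 for families. No smaller share can be had from 100 splits, and libraries may share an origin. A chance split of the libraries is thus argued against but not excluded. The highest other split gave 6161 genes and 9 families. That split keeps 10 of 12 libraries on their real side, and the median over the other splits was 0, which points to a structure that sets N2 and the double mutant against the single mutants. Depth follows the same structure. After thinning to equal counts 7992 genes and 94 families were called, 7821 of the 9121 genes in the same direction. Most calls thus do not rest on unequal counts in the fit. Fold sizes stood at 99.4% of those before, but thinning keeps expected proportions and could not remove an effect that came with depth. A batch that goes with depth stays open, and the label of the met-2 group is in doubt.

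Interaction values on the log2 scale were 6.79 for wip-1, 6.12 for sygl-1, 5.66 for sip-1 and 5.57 for serp-1.1, each low in both single mutant groups. They were -16.09 for col-77, -14.92 for col-74, -14.48 for col-125 and -14.01 for col-65, each high in both; col-125 has 3 counts over N2, and values of this size depend on the prior count. Among repeats, where (CTCG)n has 3 counts over set-25 so that its value depends on the prior count too, they were 5.41 for (GGGAA)n, 5.32 for (CAG)n, 5.10 for (CTACT)n, 4.89 for (GA)n, 4.36 for (TC)n, 4.25 for (CTCG)n, 3.63 for CER16-I_CE and 3.52 for CER7-LTR_CE. Below the sum lay (AAATG)n at -5.39, (TAAA)n at -6.15, (TAG)n at -7.04 and (TAGA)n at -7.71. In set-25 (TAAA)n stood at 3.87 ± 6.16 CPM and (TAGA)n at 35.2 ± 58.9 CPM. With an SD so far above the mean, both values rest largely on a single set-25 library. (TAAA)n lost its call without N2 libraries a, b and c (adjusted p = 0.0875, 0.0964 and 0.1002), met-2 libraries b and c (0.0994 and 0.0588) and double-mutant libraries a, b and c (0.108, 0.0933 and 0.0989). (TAGA)n lost its call without N2 libraries a, b and c (adjusted p = 0.0722, 0.0935 and 0.0812), met-2 library b (0.0648) and double-mutant libraries a, b and c (0.0917, 0.0776 and 0.0930).

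In the libraries labelled met-2 the RNA of met-2 stood near its N2 level, with a log2 change of -0.27 (adjusted p = 0.0757), and -0.40 (adjusted p = 0.0128) without library c. An allele that leaves a full level of transcript is argued against by the double mutant, whose label gives the same allele and whose met-2 RNA changed by -2.62 on the log2 scale. Libraries without the deletion under this label stay open and untested, since the value of -0.27 (-0.266) that raised the question cannot also support them. A swap within the 12 libraries has no partner, since no library of another group is out of place by its met-2 or set-25 RNA. No biological explanation was tested.

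In both single mutant groups 4569 genes changed alike and were not called in the double mutant, 2143 higher, among them col-125, and 2426 lower, among them wip-1. This is partly a matter of the threshold: their median log2 change in the double mutant was 0.75 for the higher and -0.13 for the lower genes, and with only the 6 libraries compared 757 and 746 of them were called there in the same direction. After thinning, fold sizes stood at 97.3% of those before. Thinning keeps expected proportions, so this value was largely fixed in advance and no conclusion is drawn from it. Thinning could not remove an effect that came with depth when the libraries were made. Depth as a marker of a separate batch stays open, with 79.95% of the genes still called after thinning, as do gene length (Spearman rho 0.0956, SE 0.0149, across genes, which are not independent, but -0.240 among the higher, 0.443 among the lower and 0.257 over all genes in the double mutant) and reads from introns (rho 0.193). Older embryos in the single mutant libraries may explain part of it: the difference between set-25 libraries c and a, of 1 genotype, ran along the same genes with rho 0.789. It had the same sign in 74.6% of them. These genes were chosen in part by calls in set-25, which use libraries a and c, so part of that rho may be built in. The difference also followed the met-2 and double-mutant changes over all genes, both with rho 0.686. The labels do not say which library holds older embryos. Loss of a single methyltransferase stays open and cannot be told apart from these, since 0 N2 libraries lie at the depth of the single mutants.

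Genes higher in the double mutant lay on chromosome arms more often, with an odds ratio of 1.2. Within 5 classes of expression the ratio was 1.07 (0.926 to 1.23), so low expression of arm genes could account for it, though 1.23 lies above the value of 1.2 to be explained. Without the clustered F-box, MATH and BTB, chemoreceptor, lectin and nuclear hormone receptor families it was 1.19 (1.03 to 1.38). The ratio hardly moved, so these families alone do not account for it, with the limit that clustered genes are not independent. Shared reads among other genes were not tested. Loss of H3K9 methylation on arms stays open, as untested, since no methylation data were used here.

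With 10 splits of 6 libraries no share under 0.05 can be had. Refitted with the 6 libraries alone, the real split and the highest other gave 9164 and 0 genes for the libraries labelled met-2 against N2, 4043 and 0 for set-25, 6114 and 0 for the double mutant, 8903 and 0 for the double mutant against met-2, 3912 and 0 against set-25, and 3 and 0 for met-2 against set-25. Repeat families gave, in the same order, 132 and 0, 32 and 0, 61 and 0, 147 and 0, 55 and 0, and 12 and 1. In each of these 12 cases 1 of 10 splits, the real one, gave as many. Gene lists gave 21 with 26 in the highest other split for the libraries labelled met-2, 15 and 19 for set-25, and 15 and 20 for the double mutant, and 6, 5 and 5 of the 10 splits gave as many. The number of lists called therefore cannot be told from that of other splits.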

How the results depend on the processing

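Alternatives chosen after seeing the data were library totals, thinned counts, only the libraries compared for repeats, no libraries labelled met-2, and the letter as a block; the cause was not tested unless given. The replicate numbers of the titles cannot be matched to columns, so a block by number was not run. Libraries that share a letter did not deviate together across genes (r from -0.647 to 0.297 over 18 pairs, 4 of them over 0.1), and 11 of 36 comparisons of a library with another genotype were best with its own letter. Still, ribosomal RNA shares order the letters alike in all 4 genotypes, a hint that the letter may mark a batch. With the letter as a replicate block 741 genes were called for the double mutant (594 higher, arm odds ratio 1.499) and 1841 for met-2 against set-25, and the other totals of genes, families and lists stayed within 1.5 times. Repeat shares lay below the N2 library of the same letter in each of 9 mutant libraries, with differences of -0.0445, -0.241 and -0.178 in met-2, -0.0664, -0.176 and -0.0575 in set-25 and -0.0492, -0.127 and -0.0501 in the double mutant for a, b and c. Median-ratio size factors, no filter on low counts, thinned counts, genes and repeats in 1 table and fits without the libraries labelled met-2 kept each total of genes and families within 1.5 times its value, and the other arm boundary kept all 3 arm results. Counts by direction moved further: the 476 decreases in the double mutant became 271 with median-ratio size factors, 285 with no filter, 125 with thinned counts and 275 without the libraries labelled met-2, and the 1324 in met-2 against set-25 became 868 with no filter and 2161 with DESeq2. With genes and repeats in 1 table the 12 family increases in set-25 became 27, and the 11 family decreases in the double mutant against set-25 became 26, 20 with median-ratio size factors, 19 with DESeq2 and 6 without the libraries labelled met-2. Of 5206 values of named genes and families under alternatives, 4807 kept direction and side of the threshold, 395 lost the call, 2 gained it and 2 reversed: met-2 RNA in the libraries labelled met-2, 0.00466 with totals, and in set-25, -0.0113 with no filter. A change of at least 2-fold leaves by its construction 5346 genes for the libraries labelled met-2, 3642 for set-25, 4301 and 2328 for the double mutant against met-2 and set-25, and 1375 for met-2 against set-25. It leaves 39, 31, 51 and 12 repeat families for met-2, set-25, the double mutant against met-2, and met-2 against set-25, and an arm odds ratio of 1.11 in the double mutant. Totals gave 160 families for the interaction and 92 for the double mutant against set-25, and 0.34 for met-2 RNA in set-25. TMM within the repeat table gave 17 families for met-2 against set-25, and DESeq2 gave 2691 genes for the double mutant (2118 higher). With only the libraries compared there were 4043 genes and 32 families for set-25, 6114 and 61 for the double mutant and 3 and 12 for met-2 against set-25. Camera called 24, 18 and 15 lists for met-2, set-25 and the double mutant, fry 27, 21 and 1, and camera with an estimated correlation 0, 0 and 0 (3, 3 and 0 at an unadjusted p under 0.05; smallest adjusted p = 0.304, 0.440 and 0.808). Without CELE45 the repeat share differed by 0.225 in met-2 and 0.00297 in set-25. Leaving out 1 library gave 368 to 777 genes for the double mutant, 88 to 6785 for met-2 against set-25, 7813 to 9421 for met-2, 4920 to 8047 for set-25, 6031 to 7982 and 3666 to 6429 for the double mutant against met-2 and set-25, and 8414 to 10307 for the interaction. For families it gave 72 to 126 for met-2, 35 to 57 for set-25, 18 to 26 for the double mutant, 82 to 125 and 45 to 75 for the double mutant against met-2 and set-25, 75 to 108 for met-2 against set-25 and 64 to 136 for the interaction. Lists numbered 21 to 24, 13 to 18 and 14 to 16, arm odds ratios ran from 0.748 to 0.796, 0.666 to 0.769 and 1.21 to 1.79, and share differences from -0.187 to -0.0982, -0.133 to -0.0435 and -0.108 to -0.0188. At this depth, and with the same spread in all genotypes, changes of 1.5-fold were recovered in 17.9 to 25.4% of simulated cases.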

Other observations

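The tests in this part were set before their results were seen.

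Some lists did not pass camera in any comparison with N2. Camera adjusted p for the libraries labelled met-2, set-25 and the double mutant, in this order here and below, was 0.970, 0.491 and 0.165 for 11 spermatogenesis genes, 0.133, 0.336 and 0.125 for 6 yolk and adult soma genes and 0.886, 0.301 and 0.389 for 17 heat shock and unfolded protein genes. It was 0.126, 0.0669 and 0.963 for 11 dosage compensation genes, 0.685, 0.0737 and 0.609 for 79 MATH and BTB genes and 0.923, 0.906 and 0.726 for 201 chemoreceptors. It was 0.923, 0.328 and 0.777 for 35 glutathione S-transferases, 0.923, 0.716 and 0.213 for 17 piRNA loci, 0.978, 0.143 and 0.538 for 14 insulin-like genes and 0.412, 0.613 and 0.623 for 5 small nematode-specific peptides, whose median in the double mutant was -0.39, or 0.89 with a gene without counts at its bound.

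Genes higher in the double mutant included 62 annotated pseudogenes, 5.00% against 3.103% of other tested genes (odds ratio 1.64, 1.23 to 2.17, Fisher's exact p = 7.72e-04). A loss of silencing at pseudogenes may contribute, as may reads shared with their parent genes. Neither was tested, and the ratio does not allow for expression level. Of these higher genes 688 stood under 1 CPM in N2, 55.4% against 26.1% (odds ratio 3.53, 3.13 to 3.98). The same N2 libraries are the base of the change that calls a gene higher. The filter by genotype can also pass a gene low in N2 through a mutant group. An excess is therefore partly built in and no conclusion is drawn from it, although genes with few counts also need a larger change to be called. Many variants linked to the 2 mutations on chromosome III could raise that chromosome's share of called genes. It held 230 of them, 13.4% against 15.8% of other genes (odds ratio 0.825, 0.709 to 0.956, Fisher's exact p = 0.00946), so no excess was seen. The ratio does not allow for expression level, and it could miss a few linked variants or variants on other chromosomes.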
